A study of Mus musculus with 5 samples.

How the data were processed

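The data are 5 whole-transcript exon arrays of N2A mouse neuroblastoma cells, with 1 array of control siRNA, 2 of Fus siRNA and 2 of FET siRNA (Fus, Ewsr1 and Taf15 together), from RNA taken 48 h after transfection. Per the labels' protocols, siRNA was delivered with a cationic lipid reagent and total RNA was turned into biotin-labelled sense-strand DNA with the array maker's kits. The authors deposited 1 table of log2 values per probeset, and per the submitters' processing notes these were made with RMA in Affymetrix Expression Console, with mm9 named as the genome build. RMA corrects the background, normalises between arrays and summarises the probes of a probeset on the log2 scale, so values near the floor are compressed and differences of weakly expressed exons are understated. Versions of these tools are not given in the sources used here. The deposited log2 values were used as they are. The arrays have no read depth. The number of arrays limits the precision, and about 50% of the probesets lie below the minimum used here.

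The groups of the control and Fus samples were taken from their siRNA label and those of the FET samples from their titles, and the same labels give the number of the siRNA set in each knockdown group. Every array of the table belongs to the series. Of 1195555 probesets, 319246 carry 1 gene symbol in the platform's annotation, 7654 carry several and 868655 carry none, and only those with 1 symbol were used by name. Of 22345 symbols, 18036 are current in the GRCm38.p6 gene table, 4244 were updated through a single synonym, and 65 were kept as written. That table was used for names and gene span only, and no coordinates are given because its assembly is not the one named for the arrays. Probesets were kept when their mean over the 5 arrays was at or above 5.53 log2 units, the median of all rows. A gene value is the median over its kept probesets, at least 3 of them, and was obtained for 16024 genes. The level of Fus was not analysed here.

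Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), all 5 arrays in 1 fit with the groups control, Fus and FET, and adjusted after Benjamini and Hochberg with a threshold of 0.05. The fit has 2 residual degrees of freedom, from the pairs of knockdown arrays, and the lone control is assumed to vary like them. Errors given as SE are limma's moderated standard errors, and errors given as SD are over the 2 arrays of a group. Genes at least 1.5-fold to one side in both arrays of a group were counted, and the count was repeated for every choice of a reference array other than the control with 2 further arrays and for 100 simulated data sets without an effect. Exon use was tested by subtracting the gene value from each probeset, in genes with at least 4 kept probesets. Tables were handled with data.table (version 1.17.8) and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

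Before the data were examined, 20 gene lists were fixed. They are the FET family, nuclear RNA-binding proteins, cleavage and polyadenylation factors, proteins of the U1, minor spliceosome and U7 snRNPs, replication-dependent histones, long-intron neuronal genes, interferon response, p53 targets, G2/M cell cycle, DNA replication, DNA damage repair, integrated stress and unfolded protein response, cholesterol biosynthesis, oxidative phosphorylation, cytoplasmic ribosomal proteins, neuronal and sympathoadrenal markers, small RNA pathway, nuclear and host-gene long non-coding RNAs, immediate early genes, and markers of other cell types. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 60 list tests, and again with an estimated correlation. With an estimated correlation camera also takes its degrees of freedom from the fit, which has 2. A list can therefore fail there without its members being correlated. Members were also adjusted over the list alone. The rule for named genes was fixed at the same time. It takes the siRNA targets, then up to 10 genes per direction past the threshold or, where fewer pass, those of smallest limma p among genes at least 1.5-fold in both arrays, and per list the members past the threshold or else the 2 of largest absolute difference. Gene models, clone names, olfactory and vomeronasal receptors and microRNA hosts were counted and not named in the second part, and a target probeset could be named in the exon test.

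Each step was tested on simulated data with 200 changed features per comparison. For Fus versus control on 16024 genes, 4% of the genes changed by 1 log2 unit were called, 66% at 2, 94% at 3 and 100% at 4. For FET versus control the shares were 0%, 60%, 96% and 98%, and for FET versus Fus 8%, 78%, 98% and 100%. In the exon test on 224465 probesets 0% were called at any of these sizes. A list of 42 genes shifted by −0.3 in 1 group was called by camera in both comparisons that hold that group. The simulated genes varied independently, whereas this list (DNA replication) had an estimated correlation of 0.494 in the data. The simulation therefore does not test whether the preset correlation is apt. Alternatives tried were another filter on low values or none, the mean of probesets, quantile normalisation or median centring of the arrays, eBayes with a trend, the siRNA number as a block, only the arrays of a comparison, and leaving out each array.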

Results

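Gene expression was measured in N2A cells, an established mouse neuroblastoma line (also called Neuro-2a), 48 h after transfection with small interfering RNAs (siRNAs). Each of the 5 samples was hybridised to its own Affymetrix mouse exon array, on which short probesets report single exons and the probesets of a gene can be combined into a gene value. There was 1 array of cells given control siRNA, 2 arrays of cells given siRNA against Fus, and 2 arrays of cells given siRNAs against Fus, Ewsr1 and Taf15 together, called FET here after the protein family that these genes encode. The FET proteins bind RNA and DNA in the nucleus. Arrays 1 and 2 of a knockdown group carried differently numbered siRNA sets, so the spread between them holds the siRNA together with any difference in handling. The labels do not say which of the arrays came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical. With a single control array, no spread of the control was measured, and the number of arrays limits the precision of every value. The arrays held 1195555 probesets each, with median log2 values between 5.53 and 5.57. Gene values were obtained for 16024 genes from 228356 probesets, with a median of 11 probesets per gene. Across these genes the second Fus array and the first FET array differed least, with an SD of the difference of 0.258 log2 units, whereas the other 9 pairs of arrays differed with SDs of 0.365 to 0.456.

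The siRNA targets were examined first, as a check of the labels. Ewsr1 stood at a log2 value of 10.74 in the control array, 11.02 ± 0.20 (SD, n = 2) in the Fus arrays and 10.29 ± 0.27 (SD, n = 2) in the FET arrays. Taf15 stood at 10.03 in the control, 9.90 ± 0.15 (SD, n = 2) in the Fus arrays and 9.28 ± 0.37 (SD, n = 2) in the FET arrays. Both genes were lower in each FET array than in the control and in either Fus array. Ewsr1 was lower by 0.73 log2 units in FET than in Fus (difference −0.73, SE 0.23), and Taf15 differed by −0.62 (SE 0.25). Against the control, the FET differences were −0.45 (SE 0.28) for Ewsr1 and −0.75 (SE 0.30) for Taf15. Over all genes tested, limma gave adjusted p-values of 0.874 or more for these differences. Adjusted over the list alone, both targets passed in FET versus Fus, with a smallest adjusted p of 0.0368, and neither passed in FET versus control, with a smallest adjusted p of 0.0923. Of the 36 Ewsr1 probesets used, 31 were lower in both FET arrays than in the control and both Fus arrays, and 4 were higher in both FET arrays than in the control. A gene value is a median taken on each array, so its difference need not equal the typical change of a probeset and can understate it. Between FET array 1 and Fus array 2 the Ewsr1 probesets had a median difference of −0.88, where the gene values were 10.48 and 11.16. In the Fus arrays Ewsr1 differed from the control by 0.28 (SE 0.28) and Taf15 by −0.13 (SE 0.30), and the sign for Taf15 turned when probesets were averaged by their mean. The level of Fus itself was not analysed here, so the label of the Fus arrays was not checked by its target.

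**Figure D1:**
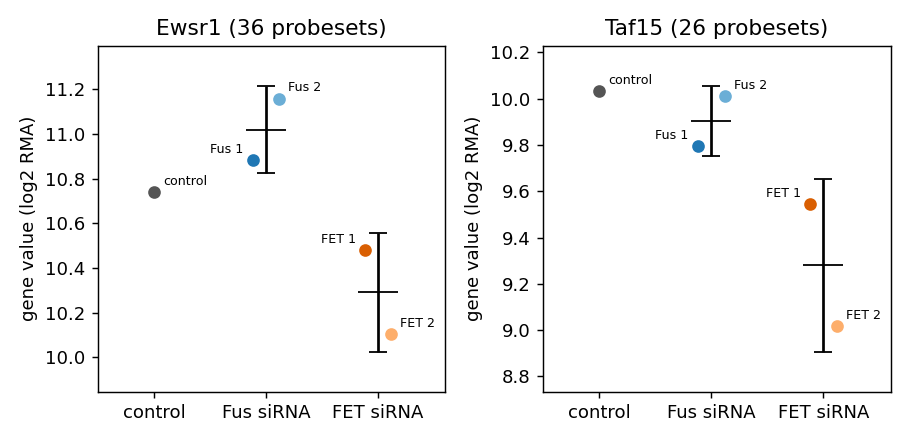
Gene values of Ewsr1 and Taf15 (log2 RMA, y axes not starting at 0) in each of the 5 arrays, by siRNA group; the horizontal bar and whiskers give the mean and SD of 2 arrays. Both FET arrays lie below the control and both Fus arrays for either gene, at means of 10.29 for Ewsr1 and 9.28 for Taf15.

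The first comparison asked which genes differ after knockdown of Fus alone. Among the genes at least 1.5-fold higher than the control in both Fus arrays, those with the smallest p included Pdcd4, an inhibitor of translation initiation, at 1.98 log2 units above the control (SE 0.25, 3.96-fold). Acp1, a low molecular weight phosphatase, was 1.59 higher (SE 0.24), Bivm 1.54 higher (SE 0.23), and Kcnmb2, an accessory subunit of calcium-activated potassium channels, 1.66 higher (SE 0.28). Crebrf, a regulator of CREB3, and Nfic, a nuclear factor I transcription factor, differed by 1.27 (SE 0.23) and 1.17 (SE 0.24). On the lower side, Adgra1, an adhesion G protein-coupled receptor, and the membrane protein gene Cmtm4 each differed from the control by −1.74 (SE 0.27 and 0.30). The condensin subunit gene Smc2 differed by −1.36 (SE 0.26), the cadherin gene Cdh18 by −1.32 (SE 0.26), and Igfbp4, which binds insulin-like growth factors, by −1.47 (SE 0.32).

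Further genes were named by the same rule for Fus versus control. Higher values were found for Cmtm1 (1.2), Lrrc2 (1.14), Kir3dl2 (1.15) and the pseudogene Znf41-ps (1.07), of which Kir3dl2 turned to −0.35 without the filter on low values. Lower values were found for the matrix protein genes Npnt (−1.33) and Sparcl1 (−1.52), the prostaglandin D synthase gene Hpgds (−1.12), the translational repressor gene Nanos1 (−1.10) and the ceramidase gene Acer2 (−1.02). In all, 231 genes were at least 1.5-fold higher and 210 at least 1.5-fold lower than the control in both Fus arrays. None of the 16024 genes passed limma's test at a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p being 0.999. At an unadjusted p under 0.05 there were 480 genes, 262 higher and 218 lower, where chance gives 801.2. Taking another array as the lone reference against another pair of arrays gave at least as many genes 1.5-fold to one side in 18 of 24 such choices. Simulated arrays without any effect gave 790 on average (728 to 896). The simulation took its spread from the fit, and so from the pairs of knockdown arrays. The 2 Fus arrays differed more from each other (SD 0.414) than from the control (0.365 and 0.389), so 790 may be too high as a count without an effect.

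Genes of cell division and DNA synthesis were lower as sets in the Fus arrays when camera used its preset correlation, and none of these lists passed with an estimated correlation. Of 35 measured G2/M genes, which act in mitosis, 19 were lower in both Fus arrays and 3 higher in both, with a median difference of −0.22 (preset correlation, adjusted p = 0.000753, against 0.99 with an estimated one). Anln and Cdc25b, which act in cytokinesis and mitotic entry, differed by −0.71 (SE 0.31) and −0.69 (SE 0.35). Of 42 DNA replication genes, 24 were lower in both arrays and 2 higher in both, with a median of −0.31 (adjusted p = 0.000753, against 0.99), and among them the clamp loader gene Rfc1 differed by −0.77 (SE 0.52) and the polymerase gene Pold1 by −0.68 (SE 0.23). Of 33 DNA damage repair genes, 17 were lower and 7 higher in both arrays, with a median of −0.19 (adjusted p = 0.0192, against 0.99). Xrcc6, which encodes the Ku70 end-binding protein, differed by −0.74 (SE 0.29) and the Fanconi anaemia gene Fanca by −0.67 (SE 0.31). No single member passed, over all genes or adjusted over the list alone. The shift lay mainly in the first Fus array, where the list medians minus the control were −0.41 for G2/M and −0.41 for DNA replication, against −0.02 and −0.07 in the second. Without the first Fus array the adjusted p rose to 0.572 for G2/M, 0.632 for DNA replication and 0.394 for DNA damage repair.

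The other 17 lists did not pass in Fus versus control. Closest was the integrated stress and unfolded protein response, with a median of −0.15 over 37 genes (adjusted p = 0.0510), in which the chaperone cofactor gene Sdf2l1 differed by −0.92 (SE 0.57) and the transcription factor gene Atf5 by −0.83 (SE 0.25). Cholesterol biosynthesis had a median of −0.18 over 20 genes (adjusted p = 0.147), with Pmvk at −0.71 (SE 0.31). Groups of RNA-processing genes had medians near 0. The median was 0.03 for 56 nuclear RNA-binding proteins, 0.05 for 24 cleavage and polyadenylation factors, −0.04 for 27 proteins of the U1, minor spliceosome and U7 snRNPs, −0.06 for 18 small RNA pathway genes and −0.04 for 18 nuclear and host-gene long non-coding RNAs. Within them, the splicing factor gene Srsf2 differed by −0.76 (SE 0.66), the U1 protein gene Snrnp70 by 0.63 (SE 0.29) and the poly(A)-binding protein gene Pabpc4 by −0.75 (SE 0.31). Among 28 p53 targets (median 0.06), Trp53inp1 differed by 1.01 (SE 0.32) and Ei24 by −0.98 (SE 0.33). Among 25 immediate early genes (median 0.01), the phosphatase gene Dusp6 differed by 0.91 (SE 0.28) and Arc by −0.73 (SE 0.28). Medians were 0.04 for 30 interferon response genes, −0.07 for 74 oxidative phosphorylation genes, −0.03 for 69 cytoplasmic ribosomal proteins, 0.03 for 32 neuronal and sympathoadrenal markers, −0.02 for 30 long-intron neuronal genes and 0.06 for 5 replication-dependent histones. Markers of other cell types had a median of 0.01 over 19 genes (adjusted p = 0.827). The median and camera's direction had opposite signs for histones, long-intron neuronal genes, interferon response, p53 targets and the markers of other cell types, with adjusted p-values of 0.485 to 0.997.

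The second comparison asked which genes differ when all 3 FET genes are targeted. Pdcd4 had the smallest p among the genes higher in both arrays, at 2.37 above the control (SE 0.25, 5.17-fold). It was followed by Acp1 at 2.0 (SE 0.24), Bivm at 1.85 (SE 0.23) and Crebrf at 1.46 (SE 0.23). This comparison and the first use the same control array, so a low control value alone would raise a gene in both. The zinc finger gene Zfp563 was 1.66 higher (SE 0.29), Nfic 1.39 (SE 0.24), and Tfpi, the tissue factor pathway inhibitor, 1.36 (SE 0.24). Among the lower genes, Nxpe4 differed from the control by −2.01 (SE 0.26, 4.02-fold lower), Adgra1 by −2.06 (SE 0.27), Pter by −2.25 (SE 0.40) and the metalloprotease gene Adam12 by −1.99 (SE 0.28). The kinetochore gene Spc24 differed by −1.35 (SE 0.23), the long non-coding RNA gene Eldr by −1.70 (SE 0.24), and Nanos1 by −1.41 (SE 0.24).

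Further genes named for FET versus control were Cebpzos (1.49), the cytochrome c oxidase assembly gene Cmc1 (1.33) and the deubiquitinase gene Usp11 (1.24) on the higher side, and Olfml3 (−1.75), the amino acid transporter gene Slc16a10 (−1.39) and the imprinted gene Phlda2 (−1.38) on the lower side. Counted over all genes, 422 were at least 1.5-fold higher and 394 at least 1.5-fold lower than the control in both FET arrays. None passed limma's test, with a smallest adjusted p of 0.732. A crossed replicate block (Fus array 1 with FET array 2), chosen after seeing that the arrays resembled each other in this way, called 92 genes here, 13 in Fus versus control and 19 in FET versus Fus. At an unadjusted p under 0.05 there were 868 genes, 434 in each direction, where chance gives 801.2. Another array as the reference gave at least as many 1.5-fold genes in 9 of 24 choices. The total of 816 genes lay within the range of the simulated arrays without an effect (790 on average, 728 to 896). The simulation took its spread from the pairs of knockdown arrays here too.

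G2/M and DNA replication genes were also lower as sets in the FET arrays. Of the 35 G2/M genes, 20 were lower and 2 higher in both arrays, with a median of −0.29 (adjusted p = 0.000753), and of the 42 replication genes 24 were lower and 1 higher, with a median of −0.25 (adjusted p = 0.00108). With an estimated correlation both had an adjusted p = 0.99. Cdc20, an activator of the anaphase-promoting complex, differed from the control by −1.11 (SE 0.24), Ccnf by −0.86 (SE 0.25), and the single-strand DNA-binding protein gene Rpa1 by −0.99 (SE 0.24). None of the members passed over all genes or adjusted over the list alone. Here the second FET array carried most of the shift, at −0.52 for G2/M and −0.48 for DNA replication, against −0.15 and −0.05 in the first. Without the second FET array the adjusted p was 0.631 for G2/M and 0.879 for DNA replication.

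**Figure D2:**
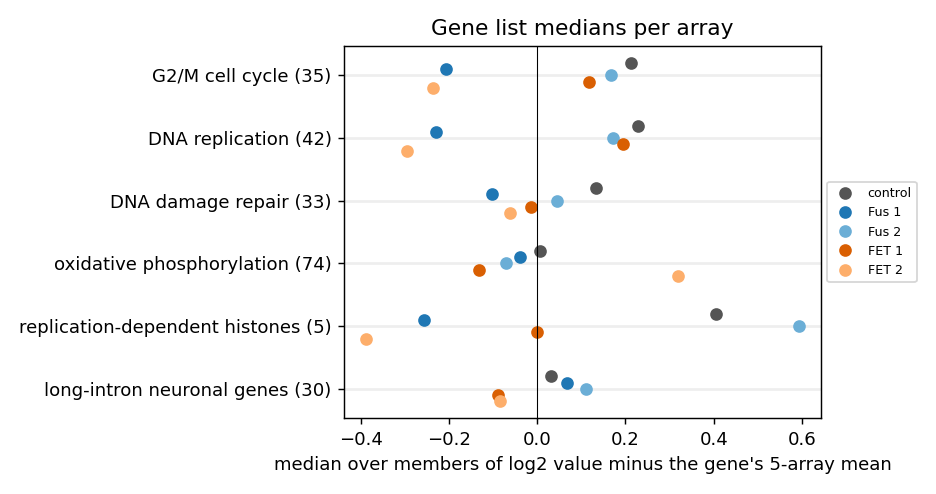
Median over the measured members of each list (number in brackets) of the log2 gene value minus that gene's mean over 5 arrays, 1 point per array. For G2/M and DNA replication the first Fus array and the second FET array lie at −0.21 to −0.30 and the other 3 arrays between 0.12 and 0.23, while for long-intron neuronal genes both FET arrays (−0.09) lie below the other 3.

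The other 18 lists did not pass in FET versus control, with adjusted p-values from 0.0570 to 0.997. DNA damage repair had a median of −0.10 (adjusted p = 0.0570), with Xrcc6 at −1.02 (SE 0.29) and Prkdc, the DNA-dependent protein kinase, at −0.82 (SE 0.24). The 5 measured histone genes had a median of −0.65 (adjusted p = 0.0910), with H1f2 at −1.71 (SE 0.67) and H4c12 at −1.51 (SE 0.74). Histone values are uncertain because near-identical copies can share probes. Oxidative phosphorylation had a median of 0.08 (adjusted p = 0.126), and 2 ATP synthase subunit genes, Atp5md and Atp5l, differed by 1.49 (SE 0.36) and 1.19 (SE 0.25). Cholesterol biosynthesis stood at −0.27 (adjusted p = 0.126) and cleavage and polyadenylation factors at 0.17 (adjusted p = 0.264), with the termination factor gene Pcf11 at 0.75 (SE 0.24). Among other RNA-binding and snRNP genes, Snrnp70 differed by 0.92 (SE 0.29), Snrpd1 by 0.97 (SE 0.43), Sfpq by −0.77 (SE 0.32) and Ptbp2 by 0.80 (SE 0.66). The nuclear receptor gene Nr4a2, an immediate early gene, differed by 1.41 (SE 0.28), and the p53 target Trp53inp1 by 1.30 (SE 0.32). In the stress list, Sdf2l1 differed by −1.78 (SE 0.57) and the cystine transporter gene Slc7a11 by 1.17 (SE 0.53). Markers of other cell types had a median of 0.12 (adjusted p = 0.827). The median and the test differed in sign for the U1, minor spliceosome and U7 proteins and for neuronal markers, and the mean did so for the small RNA pathway.

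The third comparison set FET against Fus and did not use the control array in its difference. By their labels, the groups differ in the added siRNAs against Ewsr1 and Taf15. The labels do not say whether a FET array held the same Fus siRNA as the Fus array of its number. Across genes the differences of the 2 same-numbered pairs correlated at r = −0.336, where simulated arrays without an effect gave −0.004, so the pairs did not share a direction. Cox20, which encodes an assembly factor of cytochrome c oxidase, was 1.41 higher in FET (SE 0.22), Catsperz 1.48 (SE 0.35), Hgd, an enzyme of tyrosine breakdown, 1.30 (SE 0.30), and the ubiquitin protease gene Zup1 1.21 (SE 0.27). Kcnmb2 differed by −2.03 (SE 0.23, 4.09-fold lower), Pter by −1.70 (SE 0.33) and Nxpe4 by −1.44 (SE 0.21). Slc18a1, the vesicular monoamine transporter 1, differed by −1.55 (SE 0.26), and Alk, a receptor tyrosine kinase of neuroblastoma cells, by −1.10 (SE 0.19). Kcnmb2 stood at 7.59 in the control, 9.48 and 9.02 in the Fus arrays and 7.28 and 7.15 in the FET arrays.

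**Figure D3:**
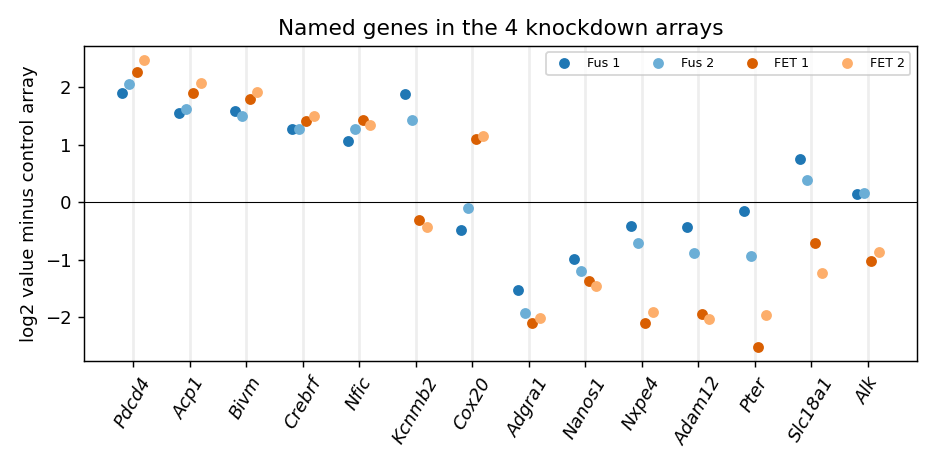
Log2 gene value minus the control array for 14 of the named genes, 1 point per knockdown array. Pdcd4, Acp1, Bivm, Crebrf and Nfic lie above 0 in all 4 arrays and Adgra1 and Nanos1 below 0, whereas Kcnmb2 lies above 0 in both Fus arrays and below it in both FET arrays.

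Smaller positive differences in FET versus Fus were those of Fkbp7 (1.12), Igflr1 (1.01), the gonadotropin-releasing hormone gene Gnrh1 (0.92), the chromatin reader gene Ing5 (0.87), Susd3 (0.85) and Ufc1 (0.82), and the remaining negative ones were Adam12 (−1.33), Tmem230 (−1.23), Fam120c (−1.18), the transporter gene Slc47a1 (−1.15) and Eldr (−1.02). In this comparison 34 genes were at least 1.5-fold higher and 65 at least 1.5-fold lower in both pairs of same-numbered arrays. With the pairs crossed, an alternative chosen after seeing the data, the counts were 37 and 108. None passed limma's test, with a smallest adjusted p of 1.0, and 405 genes had an unadjusted p under 0.05, of which 148 were higher and 257 lower, against 801.2 by chance.

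Long-intron neuronal genes, which encode synaptic and adhesion proteins over very long introns, were lower as a set in FET than in Fus. Of the 30 measured, 14 were lower in both pairs and 2 higher in both. The median was −0.19 (camera adjusted p = 0.000753, and adjusted p = 0.99 with an estimated correlation). The estimated correlation of this list was −0.012, below the preset 0.01. Its higher p there (0.0389 before adjustment) thus came with the 2 degrees of freedom and not with correlated members. Rbfox1, a splicing regulator, differed by −0.84 (SE 0.25) and Gpc6, a glypican, by −0.81 (SE 0.37). No member passed over all genes or adjusted over the list alone. Rbfox1 stood at 7.79 in the control, 8.82 and 8.26 in the Fus arrays, and 7.77 and 7.61 in the FET arrays, so it lay higher in Fus with FET near the control. Gpc6 differed by −1.56 in the first pair and −0.06 in the second. Against the control, the list's median was −0.02 for Fus and −0.18 for FET. The 74 oxidative phosphorylation genes were higher as a set, 30 in both pairs and 4 lower in both. Their median was 0.13 (adjusted p = 0.00152, and adjusted p = 0.99 with an estimated correlation of 0.561). Ndufb10 differed by 0.81 (SE 0.31) and Atp5md by 0.71 (SE 0.30). The median turned to −0.08 without the second FET array (adjusted p = 0.631). The 5 histone genes had a median of −0.29 (adjusted p = 0.0361, and adjusted p = 0.99 with an estimated correlation), which became 0.01 without the second Fus array (adjusted p = 0.842) and −0.16 without the second FET array (adjusted p = 0.536).

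The siRNA targets themselves formed the fourth list that passed in FET versus Fus. Their median was −0.68 over Ewsr1 and Taf15 (adjusted p = 0.00366, and adjusted p = 0.99 with an estimated correlation of 0.970). Without the second Fus array the adjusted p was 0.103 and without the second FET array 0.156. The remaining 16 lists had adjusted p-values of 0.177 to 0.997. Medians were −0.02 for G2/M and −0.02 for DNA replication. In same-numbered pairs the medians of the first and second pair were opposite, at 0.30 and −0.41 for G2/M and 0.43 and −0.43 for DNA replication. Across numbers the arrays lay closer. Minus the control, the G2/M and DNA replication medians were −0.41 and −0.41 in Fus array 1 and −0.52 and −0.48 in FET array 2. In Fus array 2 they were −0.02 and −0.07, and in FET array 1 −0.15 and −0.05. Cdc20 differed by −0.62 (SE 0.20). In other lists, Dusp6 differed by −0.86 (SE 0.23), Nr4a2 by 0.72 (SE 0.23) and the interferon-induced gene Mx2 by −0.71 (SE 0.27). The median and the test differed in sign for DNA damage repair and immediate early genes, and the mean did so for p53 targets.

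The Fus and FET differences from the control were set against each other. Across genes they correlated with r = 0.736, and simulated groups without an effect that share the control gave r = 0.668. The covariance was 0.0872, against 0.0985 in the simulation, a difference of −0.0113. Genes are not independent replicates. The shared control may account for part or all of the correlation, since the covariance did not exceed the simulated one, and its share cannot be split off. In all 4 knockdown arrays, 105 genes were at least 1.5-fold higher and 92 at least 1.5-fold lower than the control. Independent lists would share 6.08 and 5.16. Simulated arrays with a shared control gave 266 on average in both directions together. Because the simulated covariance exceeded the one seen, 266 may be too high as a count without an effect. Pdcd4, Acp1, Bivm, Crebrf and Nfic were among the higher genes, and Adgra1, Cmtm4 and Nanos1 among the lower. Of all genes, 4 (Pdcd4, Acp1, Bivm and Adgra1) lay at least 1.5 log2 units to one side of the control in all 4 arrays. Simulated arrays without an effect gave 9.86 such genes on average (2 to 24), a count that may be too high for the same reason. The FET difference of array 1 correlated with that of Fus array 2 at r = 0.815, whereas the other 3 combinations of a Fus and a FET array gave 0.375 to 0.507. The differences of arrays 1 and 2 correlated across genes at r = 0.397 for Fus versus control and 0.510 for FET versus control, where a shared control alone gives 0.50, and at −0.336 for FET versus Fus.

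Exon use was tested by each probeset's value relative to its gene, over 224465 probesets of 14727 genes. No probeset passed limma's test in any comparison. The smallest adjusted p was 1.0 for Fus versus control, 0.651 for FET versus control and 0.889 for FET versus Fus. At an unadjusted p under 0.05 there were 9273, 17120 and 9716 probesets, where chance gives 11223. In simulated data on as many probesets, none of the probesets changed by up to 4 log2 units was called, so exon changes were not detectable with these arrays.

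Because Fus is known to bind within long introns, gene span was set against the difference of each gene. Spans from the GRCm38.p6 gene table were available for 99.7% of genes. Spearman's rho across genes was 0.0560 for Fus versus control, 0.0090 for FET versus control and −0.0523 for FET versus Fus. The 1599 longest genes, each of at least 128 kb, had median differences of 0.036, −0.003 and −0.033 in the same order.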

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

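This result was looked for after the gene values had been seen. Probesets without a gene symbol take no part in the gene comparisons. Of 359299 such probesets above the minimum level, 143 were at least 4-fold above the control array in all 4 knockdown arrays, which is 3.98 per 10000. Among 233874 probesets with 1 gene symbol the number was 46, or 1.97 per 10000. None of the 359299 passed limma's test in any comparison. At an unadjusted p under 0.05 there were 19191 for Fus versus control, 31844 for FET versus control and 17092 for FET versus Fus, where chance gives 17965. With a single control array a low control value alone gives such a pattern. No explanation was tested.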

How the results depend on the processing

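No gene and no exon probeset passed the threshold under any alternative fixed before the data were examined. The block by siRNA number gave 0 genes and 0 exon probesets in each comparison, and 4, 2 and 4 lists in Fus versus control, FET versus control and FET versus Fus, against 3, 2 and 4 without it. The labels do not say that a number marks a shared culture or day, so the main fit did not take the numbers as pairs. In FET versus Fus, however, the counts, the choice of named genes and the medians per pair set same-numbered arrays against each other. Same-numbered arrays deviated from their group means with a correlation of −0.50 across genes. That value goes with the closeness of Fus array 2 and FET array 1, and it does not tell crossed numbers from shared handling. Chosen after seeing this, a crossed replicate block (Fus array 1 with FET array 2) called 13, 92 and 19 genes in the same order, and with crossed pairs 145 genes were 1.5-fold to one side in FET versus Fus.

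For the same 3 comparisons, counts of genes 1.5-fold in both arrays became 50, 123 and 16 at 2-fold, and 232, 504 and 57 with the mean of probesets. With 1 array of a group left out (an alternative chosen after seeing the data), which asks for the fold in fewer arrays, they were 1598 to 1922, 2374 to 2612, and 2411 to 2760. The correlation of the Fus and FET differences, 0.736 in the main fit, was 0.753 with the mean of probesets. With an array left out it was 0.506 to 0.720, lowest without Fus array 2. Correlations between siRNA sets were 0.372, 0.477 and −0.390 with a minimum at the 75th percentile, and 0.488 (FET versus control) and −0.407 (FET versus Fus) with the mean of probesets. The rho with gene span was 0.0725 and 0.0250 for Fus and FET versus control at the 75th percentile.

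Lists past the threshold numbered 0 in each comparison with an estimated correlation, where camera has 2 degrees of freedom. The estimated correlations were 0.749 for G2/M, 0.494 for DNA replication, 0.561 for oxidative phosphorylation, 0.836 for histones and 0.970 for the siRNA targets. These lie far above the preset 0.01, so the p-values of these lists with the preset may be too small. DNA damage repair had 0.026 and long-intron neuronal genes had −0.012. FET versus control gave 4 lists without a filter on low values. With an array left out the numbers were 1 to 5 for Fus versus control (1 without Fus array 1, 5 without FET array 1), 1 to 6 for FET versus control (1 without FET array 2, 6 without FET array 1), and up to 7 for FET versus Fus (without Fus array 1). Values that changed sign were in FET versus Fus the histone median (−0.742 to 0.0119 with an array left out, highest without Fus array 2) and the oxidative phosphorylation median (−0.0825 to 0.375, lowest without FET array 2), and in Fus versus control Kir3dl2 (−0.35 without a filter) and Taf15 (0.0129 with the mean of probesets). The cause of these changes was not tested. Over 66 pairs of a named gene and a comparison, 460 of 462 values under the 7 alternatives covered (the crossed block is not one) kept their direction and 0 passed the threshold, with a lowest adjusted p of 0.732. Much of this agreement in direction was fixed in advance. Apart from the targets, these genes were named for a difference to one side in both arrays or pairs, so leaving out an array could seldom turn it. The block by siRNA number leaves each difference unchanged. The changes of sign came with the mean of probesets and without the filter, where 65 of 66 kept their direction in each. Scaling moved the median of all genes by at most 0.07. RMA values near the floor limit what can be seen of weakly expressed genes.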

Other observations

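The 5 genes in these 2 paragraphs were picked after their spread between the arrays of a group had been seen, and they stand for no wider set. Dbh, which makes noradrenaline from dopamine, stood at 9.28 in the control, 10.66 and 11.69 in the Fus arrays, and 11.34 and 7.95 in the FET arrays. Syt1, a calcium sensor of synaptic vesicles, stood at 11.35 in the control, 11.72 and 10.83 in the Fus arrays, and 9.58 and 10.61 in the FET arrays. Its difference between FET and Fus was −1.18 (SE 0.43), and limma's adjusted p was 1.0. In the list of 18 long non-coding RNAs, 5 were lower and 0 higher in both pairs, with a median of −0.09 (adjusted p = 0.177).

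Ccng1, a p53 target, stood at 10.66 in the control, 10.95 and 8.93 in the Fus arrays, and 8.60 and 11.19 in the FET arrays. Cdkn1a, the cell cycle inhibitor p21, stood at 10.64 in the control, 10.40 and 8.94 in the Fus arrays, and 9.64 and 11.02 in the FET arrays. The neuronal splicing factor gene Ptbp2 stood at 9.88 in the control, 9.42 and 10.83 in the Fus arrays, and 11.21 and 10.14 in the FET arrays. For these 3 genes the second Fus array lay nearer to the first FET array than to the first Fus array.

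In the paragraphs on the 3 patterns that follow, the tests of an exchange of arrays, of a shared number, of a shared dish, of a fall in every array, of the distance of lists from all genes, of growth and of single arrays were chosen after the results had been seen, and the tests of intensity, of gene span and expression level were not. For the adjusted p under scaling the prediction was written beforehand, but quantile normalisation was not among the alternatives planned for the lists. The second Fus array and the first FET array resembled each other across genes. An exchange of these 2 arrays between the groups is argued against by Ewsr1, whose probesets had a median difference of −0.88 between FET array 1 and Fus array 2 and were lower in 33 of 36. A trend with intensity is argued against because the correlation of same-numbered arrays stayed at −0.498 after a loess correction. A Fus siRNA shared by the same number would bring same-numbered arrays together, and these 2 arrays differ in number. That correlation was −0.496 before the correction. Both same-numbered pairs of a Fus and a FET array differed more (SDs of 0.456 and 0.436) than both crossed pairs (0.258 and 0.394). These values come from the same distances that define the pattern, so they are no independent test and no conclusion is drawn from them. A dish, day or hybridisation shared by the 2 arrays, or the same Fus siRNA under crossed numbers, may account for the SD of 0.258 between them, and these cannot be told apart because the labels give neither batches nor siRNA sequences.

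G2/M and DNA replication genes lay below the control as sets. An offset of whole arrays as the whole cause is argued against, because after quantile normalisation the 2 lists lay 0.24 to 0.33 below the median of all genes in the 2 comparisons with the control. The deposited RMA values were already normalised between arrays, so normalising them again was close to no change and is a weak test of scaling. The median of all genes was −0.002 for Fus and 0.009 for FET before this step, and 0.015 for both after it. Bootstrap intervals over the members of the 2 lists lay between −0.49 and −0.14. These intervals treat members as independent, although the estimated correlations were 0.749 for G2/M and 0.494 for DNA replication. They are therefore too narrow as a measure of the uncertainty of the shift. The adjusted p of DNA replication in Fus versus control was then 0.000592, within a range of 2.18e-08 to 0.632 over the alternatives with the preset correlation, and 0.99 with an estimated correlation. A fall of at least 0.15 in every knockdown array was not seen, as the medians were −0.022 and −0.067 in Fus array 2 and −0.146 and −0.048 in FET array 1, but a smaller fall stays open with 1 control array. A growth difference between dishes, or an effect of some siRNA sets, could separate Fus array 1 and FET array 2 from the other arrays by the gap of 0.262 seen between them, and with 1 array per siRNA set the 2 cannot be told apart.

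Long-intron neuronal genes lay lower in FET than in Fus, and an effect particular to this list was weighed against 3 other explanations. A trend with expression level is argued against, since 0.02% of 10000 random lists matched on mean level had a median as low as −0.19. A single deviating array is argued against, since the highest adjusted p with 1 array left out was 0.0302. A trend with gene span over all genes stays open, because 1.1% of random lists matched on span were as low, between the bounds set beforehand, and their median was −0.06. An effect of the added Ewsr1 and Taf15 siRNAs may remain and was not tested further, and the list's adjusted p = 0.99 with an estimated correlation.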
